A study of Mus musculus with 4 samples.

How the data were processed

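Gene expression was measured on 4 single-colour Agilent mouse oligonucleotide arrays, each carrying RNA from S-180 cells, a transplantable mouse sarcoma line. Per the labels, the cells grew in medium with 10% serum and were either left untreated or given 20 µM fluoxetine, a selective serotonin reuptake inhibitor, for 12 h. Cy3-labelled complementary RNA was made from 10 ng of RNA per sample, per the labels. There were 2 control and 2 fluoxetine samples, described in the labels as biological replicates with no word on whether equal numbers share a culture or a day or whether the cultures were separate. The p-values measure the spread between these samples only. Control 1, control 2, fluoxetine 1 and fluoxetine 2 below are these samples.

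The deposited values are spot intensity on a linear scale, extracted by the authors with Feature Extraction 12.1.0.3, per the file headers. The intensity used here was the processed signal, which is background-corrected but not scaled between arrays, per the file headers. Other columns used were the deposited yes-or-no marks for spots well above background, saturated, non-uniform or outlying among replicate spots, which the authors' software set, per the file headers. Any later normalization or test by the authors is not given in the sources used here. Each array held 62976 spots, of which 59305 were not controls. Between 51.7% and 53.5% of the non-control spots on each array were well above background, and 0 were saturated. The number of arrays limits the precision of every value.

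All 4 arrays were on 1 slide and in 1 scan, so slide and scan could not serve as a block. Both control arrays lay beside each other on the slide, as did both fluoxetine arrays, and place on the slide and group cannot be told apart. The spike-in spots read at background (5 to 15 of 350 well above it), so no spike-in scaling was made.

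Processing used R 4.3.3 and limma 3.58.1. Control spots and non-uniform spots were left out, which removed 47 probes, and the spots of the 300 probes printed 10 times were averaged. The main values were log2 of the processed signal minus the 75th percentile of each array. The files name probes by transcript accession and carry no gene symbols, so symbols came from the RefSeq gene table of assembly GRCm38.p6, matched without accession versions. Of 56605 distinct probes, 34645 matched a single symbol, covering 23771 symbols, and 21913 matched none. No coordinates are given, since the build of the array design was another one. A probe was kept when it was well above background on both arrays of at least 1 group, and a gene was represented by its brightest kept probe, leaving 13539 genes. Where a gene said to have risen or fallen had another kept probe with a change of opposite sign, the text says so.

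The comparison was fluoxetine minus control in limma (lmFit and eBayes, group as the only term, all 4 arrays), with Benjamini-Hochberg adjustment. A gene was called, and is said to have risen or fallen, at an adjusted p under 0.05. Errors after ± are the standard error of the log2 change from limma, with n = 2 arrays per group, and all changes are log2 values unless given as a fold. With 2 arrays against 2, an exact permutation test of a single gene could not go below p = 0.333. A gene that was not well above background on either array of 1 group has only a bound. It is given as at least N-fold, from the mean of the brighter group against the mean, per dim array, of the higher of the lowest signal well above background and the probe's own signal. Leaving out 1 array assumed that the lone array of its group varies like the other group.

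The groups, the test, the alternatives other than those named below as added, 26 gene lists and the rule for naming genes were fixed before the data were examined. The 24 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01. Adjusted p of a list means this test over the 24 lists. The rule named the 6 largest rises and 6 largest falls among called genes above background on all 4 arrays, the 3 largest bounds in each direction, up to 4 called members of each called list and up to 2 of each other list. For rises, falls and bounds it passed over gene models, clones and names that are accessions. For rises and falls it took only genes whose groups did not overlap. Of the genes this rule takes, 1 is not reported here and stays in the counts. Called members outside that rule are also named where a count was 5 or lower, and a few others as examples, all after their values were seen. Counts adjusted over the list alone used only the p-values of the list's members.

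The script was tested on simulated data with 13539 genes, 2 arrays per group, 200 changed genes and 20 simulations. It called 3.13% of genes changed by 0.5 log2, 76.0% of those changed by 1 and 94.6% of those changed by 2. Of the calls, 7.82% were false. Far more genes were called in the data (3653), which makes the adjusted cutoff less strict there. The shares recovered in the simulation therefore do not carry over to the data. In simulated data with no change, a mean of 0.05 genes and 0 lists were called. The simulated genes varied independently of each other, so the 0 lists cannot speak for lists whose genes vary together.

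The alternatives were normexp background correction, quantile normalization, median centring, other filters on dim probes, the mean over the probes of a gene, each probe on its own, trend and robust variance moderation, the replicate number as a block, each array left out, an estimated inter-gene correlation, and fry. Added after seeing the data were leaving out spots marked as outliers among replicate spots, crossing the replicate numbers, and adding probes without a symbol to the test. The normexp correction used the median signal in place of the mean signal, because the files used here carry no mean signal column. Probes without a symbol were left out of the gene counts and tested on their own.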

Results

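RNA of S-180 sarcoma cells was profiled after 12 h with 20 µM fluoxetine (2 arrays) or without it (2 arrays). The 75th percentile of the signal was 675 on control 1, 631 on control 2, 554 on fluoxetine 1 and 643 on fluoxetine 2. Over the 25833 probes well above background on all 4 arrays, Pearson's r across probes, which are not independent replicates, was 0.993 between the control arrays and 0.995 between the fluoxetine arrays. Between arrays of different groups it ran from 0.976 to 0.983. The first principal component held 72.6% of the variance and placed both fluoxetine arrays (35.2 and 31.2) apart from both control arrays (−41.6 and −24.8).

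The comparison asked which transcripts of the tumour cells differ in amount after fluoxetine. Genes of cholesterol synthesis and uptake, lysosomal genes, targets of the stress transcription factor ATF4, and genes of glycolysis and hypoxia were higher with fluoxetine as lists, with list medians of 0.58, 0.42, 0.40 and 0.42 (adjusted p = 0.88 for each with an estimated correlation). Genes of the extracellular matrix and mesenchymal state and genes of DNA replication were lower, with list medians of −0.61 and −0.21 (adjusted p = 0.88 for both with an estimated correlation). DNA replication was not called with fry, another set test (adjusted p = 0.0844). Single transcripts with large rises included Ddit3, which encodes the stress-induced factor CHOP (2.11 ± 0.13, adjusted p = 0.00953), the small heat shock protein gene Cryab (2.28 ± 0.08, adjusted p = 0.00644) and Nos2, the inducible nitric oxide synthase (2.88 ± 0.08, adjusted p = 0.00644). The immediate early genes Fos (−1.64 ± 0.11, adjusted p = 0.00989) and Egr1 (−1.28 ± 0.10, adjusted p = 0.0109) fell.

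In limma, 3653 of 13539 genes were called, 2276 higher and 1377 lower with fluoxetine. Of these, 620 differed at least 2-fold, 301 higher and 319 lower. Among genes above background on all 4 arrays, 242 were at least 2-fold higher and 196 at least 2-fold lower. The values of the groups did not overlap for 72.5% of tested genes, where chance gives 33.3%. The genes the naming rule took as called show this largely by their selection, and Pecam1 and Ppia, taken without a call, overlapped. The count of calls rests on few arrays: it was 989 without control 1, 2660 without control 2, 0 without fluoxetine 1 and 0 without fluoxetine 2, with 4070 and 4535 genes at an unadjusted p under 0.05 in the last pair. At least 2-fold calls numbered 552, 1006, 0 and 0 in the same order, and without a filter on dim probes limma called 0 genes, with 5272 at an unadjusted p under 0.05.

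The largest rises and falls given here are those among genes above background on all arrays that the naming rule allowed. The rises were led by Atp13a4, a P5-type ATPase (3.14 ± 0.24, adjusted p = 0.0109), Nos2, and Ampd3, an AMP deaminase (2.77 ± 0.07, adjusted p = 0.00644). They were followed by the small nucleolar RNA Snora34 (2.69 ± 0.07), Creb3l3, a membrane-bound transcription factor of the endoplasmic reticulum (2.55 ± 0.14), and Ndrg4 (2.47 ± 0.07). The largest falls were in Npm3, a nucleoplasmin family gene (−3.07 ± 0.72, adjusted p = 0.0476), Stra6, a receptor for retinol uptake (−2.92 ± 0.36, adjusted p = 0.0165), and Marchf1, a ubiquitin ligase (−2.75 ± 0.32, adjusted p = 0.0157). Pus7, a pseudouridine synthase (−2.64 ± 0.15), Mcidas (−2.59 ± 0.38) and the mitochondrial fatty acid synthesis gene Oxsm (−2.43 ± 0.16) came next. The control values of Npm3 lay far apart: its change was −2.06 without control 1 and −4.09 without control 2. Without control 1 the falls of Stra6 (−2.69), Pus7 (−2.47), Marchf1 (−2.35) and Oxsm (−2.22) were larger than that of Npm3. Mcidas also moved, to −2.05 without control 1 and −3.12 without control 2. The other kept probes of Pus7 and of Oxsm moved the other way. Cap2 was at least 8.57-fold higher with fluoxetine, the carnitine synthesis gene Bbox1 at least 6.17-fold and the beta globin gene Hbb-bt at least 5.68-fold, each not well above background in control (adjusted p = 0.0443, 0.0301 and 0.00784). The bound of Cap2 was 4.92-fold without fluoxetine 2 and 14.9-fold without fluoxetine 1, and that of Bbox1 3.20-fold and 11.9-fold. Gabra2, a GABA receptor subunit, was at least 8.02-fold lower, and the potassium channel genes Kcns1 and Kcna6 at least 7.30-fold and 4.61-fold lower, each not well above background with fluoxetine (adjusted p = 0.0109, 0.014 and 0.0485). For Kcna6 the bound was 1.70-fold without control 2 and 12.4-fold without control 1.

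Of 22 tested genes of cholesterol synthesis and uptake, 16 rose, 1 fell and 5 did not pass; adjusted over the list alone, 17 rose and 1 fell. The list was higher (adjusted p = 0.000151; adjusted p = 0.88 with an estimated correlation). Cyp51, the lanosterol demethylase, rose by 1.45 ± 0.33 (adjusted p = 0.0464), Fdft1, squalene synthase, by 1.28 ± 0.10, Msmo1, a sterol methyl oxidase, by 1.14 ± 0.09, and Insig1, a sterol sensor, by 0.88 ± 0.07. The member that fell was Tm7sf2, a sterol reductase (−0.94). Among 12 genes of fatty acid synthesis and desaturation, 3 rose, 0 fell and 9 did not pass, the same counts as when adjusted over the list alone, and the list was not called (median 0.37, adjusted p = 0.0688). Under 5 other settings it was called higher, with adjusted p from 0.00293 to 0.88 over all settings tried. The members that rose were the desaturase genes Scd2 (1.14 ± 0.10) and Scd1 (0.59) and the lipogenic regulator Srebf1 (0.70 ± 0.08). Of 6 sterol efflux genes, 2 rose, the oxysterol receptor gene Nr1h2 (0.67 ± 0.11) and the acyltransferase gene Lpcat3 (0.58 ± 0.08), and 1 fell, the lipoprotein gene Apoe (−0.50). Adjusted over the list alone the efflux counts were again 2 and 1, and the list was not called (median 0.12, adjusted p = 0.944). With fry the efflux list was called higher (adjusted p = 0.0423), though 3 of its tested members changed upward and 3 downward. The sterol transporter genes Abca1 and Abcg1, and Smpdl3a, were too dim in both groups to be tested, so the list leaves them out.

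**Figure D1:**
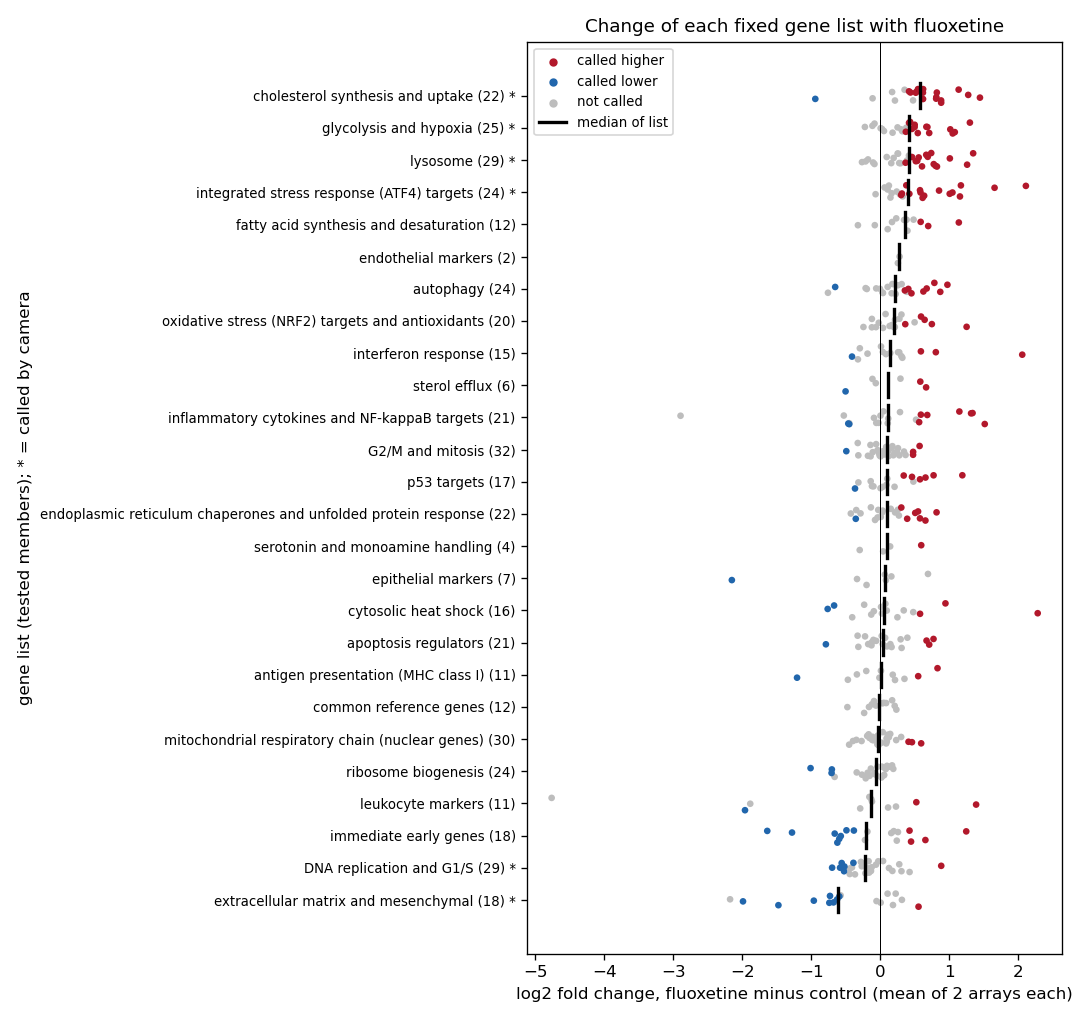
Each point is 1 tested gene of a list, placed by its log2 change (fluoxetine minus control, 2 arrays each), and coloured when called; black bars are list medians, from 0.58 for cholesterol synthesis and uptake to −0.61 for extracellular matrix and mesenchymal genes. Numbers in brackets are tested members, and asterisks mark the 6 lists called by camera.

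Lysosomal genes were higher as a list (29 tested, median 0.42, adjusted p = 0.000494; adjusted p = 0.88 with an estimated correlation). In it 15 rose, 0 fell and 14 did not pass, and adjusted over the list alone 19 rose and 1 fell. Atp6v0d1, a subunit of the lysosomal proton pump, rose by 1.35 ± 0.09, the sialidase gene Neu1 by 1.26 ± 0.12, the cholesterol exporter gene Npc1 by 1.01 ± 0.09 and the membrane protein gene Lamp2 by 0.82 ± 0.07, with adjusted p from 0.00998 to 0.0124. The protease gene Ctsd (0.28) and Lamp1 (0.16) did not pass. The autophagy list was not called (24 tested, median 0.22, adjusted p = 0.0863), but was called higher under 3 other settings, with adjusted p from 0.0029 to 0.88 over all settings tried. In it 8 rose, 1 fell and 15 did not pass, with the same 8 and 1 when adjusted over the list alone. The cargo receptor genes Sqstm1 (0.98 ± 0.11) and Optn (0.87 ± 0.08) led the rises, and the member that fell was Atg9a (−0.65).

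ATF4 targets of the integrated stress response were higher as a list (24 tested, median 0.40, adjusted p = 3.72e-05; adjusted p = 0.88 with an estimated correlation). Of these, 15 rose, 0 fell and 9 did not pass, and 16 rose and 0 fell when adjusted over the list alone. Beside Ddit3, the glutathione-degrading enzyme gene Chac1 rose by 1.66 ± 0.10, the proline synthesis gene Pycr1 by 1.17 ± 0.12 and the pseudokinase gene Trib3 by 1.16 ± 0.08, with adjusted p from 0.00953 to 0.0141. Atf4 itself (0.33) and Asns, asparagine synthetase (0.29), did not pass. Endoplasmic reticulum chaperone and unfolded protein response genes were not called as a list (22 tested, median 0.09, adjusted p = 0.459): 7 rose, 1 fell and 14 did not pass, and adjusted over the list alone 7 rose and 3 fell. With fry this list was called higher (adjusted p = 0.0443). Hyou1 (0.82 ± 0.08) and Xbp1 (0.66 ± 0.09) rose, the translocon gene Sec61b fell (−0.35), and the chaperone gene Hspa5 was at −0.03. Of the other kept probes of Hyou1, 1 moved the other way.

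In the list of NRF2 targets and antioxidants, 5 of 20 rose, 0 fell and 15 did not pass, with 5 and 0 adjusted over the list alone (median 0.21, adjusted p = 0.124). This list was not called, but was called higher under 2 other settings, with adjusted p from 0.0146 to 0.88 over all settings tried. The heme oxygenase gene Hmox1 rose by 1.25 ± 0.11, Osgin1 by 0.75 ± 0.09, Mgst1 by 0.65, G6pdx by 0.59 and Gpx4 by 0.36. Cytosolic heat shock genes went both ways: 3 of 16 rose, 2 fell and 11 did not pass, against 4 and 2 adjusted over the list alone (median 0.05, adjusted p = 0.944). Cryab, Hspb8 (0.95 ± 0.11) and Dnajb4 (0.58) rose, while the stress-inducible Hsp70 genes Hspa1a (−0.76) and Hspa1b (−0.67) fell; these 2 are near-identical copies whose probes may not tell them apart.

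Of 17 p53 targets, 6 rose, 1 fell and 10 did not pass, against 6 and 2 adjusted over the list alone, and the list was not called (median 0.10, adjusted p = 0.386). Fry called the p53 list higher (adjusted p = 0.0446). The pro-apoptotic gene Bbc3 rose by 1.19 ± 0.09 and Ccng1 by 0.77 ± 0.12, and Aen fell (−0.36), with 1 of its other kept probes moving the other way. Of 21 apoptosis regulators, 3 rose, 1 fell and 17 did not pass, against 3 and 0 adjusted over the list alone (median 0.04, adjusted p = 0.944). The survival gene Bcl2l1 (0.77 ± 0.07), Casp9 (0.71) and Birc3 (0.67) rose, and Diablo fell (−0.79 ± 0.17). The other kept probes of Casp9 and of Diablo moved the other way.

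DNA replication and G1/S genes were lower as a list (29 tested, median −0.21, adjusted p = 0.0049; adjusted p = 0.88 with an estimated correlation). In it 6 fell, 1 rose and 22 did not pass, with the same 6 and 1 adjusted over the list alone. The replication licensing gene Cdc6 fell by 0.70 ± 0.10, the GINS subunit gene Gins2 by 0.58 ± 0.09, the clamp loader gene Rfc3 by 0.56 ± 0.10 and the thymidylate synthase gene Tyms by 0.52 ± 0.07. The other kept probe of Gins2 moved the other way. The member that rose was Cdc45 (0.89), which encodes a subunit of the replicative helicase. Among 32 genes of G2/M and mitosis, 3 rose, 1 fell and 28 did not pass, against 1 and 1 adjusted over the list alone (median 0.10, adjusted p = 0.751). Hmmr (0.57 ± 0.08), Kif11 (0.48) and Bub1b (0.48) rose and the mitotic transcription factor gene Foxm1 fell (−0.49 ± 0.07). Neither other kept probe of Hmmr moved with its brightest probe, and its value over all its probes was −0.13.

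Glycolysis and hypoxia genes were higher as a list (25 tested, median 0.42, adjusted p = 0.00061; adjusted p = 0.88 with an estimated correlation). Of these, 14 rose, 0 fell and 11 did not pass, and 17 rose and 0 fell adjusted over the list alone. The enolase gene Eno2 rose by 1.30 ± 0.09, the aldolase gene Aldoc by 1.08 ± 0.07, the hypoxia-induced peptide gene Adm by 1.05 ± 0.16 and the phosphofructokinase gene Pfkl by 1.02 ± 0.11. Ldha, lactate dehydrogenase (−0.11), and Pgk1 (0.03) did not pass. In the nuclear-encoded respiratory chain, 3 of 30 rose, 0 fell and 27 did not pass, against 1 and 0 adjusted over the list alone. Its median (−0.03) and test (lower, adjusted p = 0.683) differed in sign from its mean (0.01). The members that rose were Cyc1 (0.59 ± 0.08), Sdhc (0.41) and Atp5b (0.46 ± 0.10), and neither other kept probe of Atp5b moved with it. Of 24 ribosome biogenesis genes, 3 fell, 0 rose and 21 did not pass, with the same counts adjusted over the list alone (median −0.06, adjusted p = 0.107). They were the pseudouridine synthase gene Dkc1 (−1.01 ± 0.11), Wdr43 (−0.70 ± 0.08) and Nop56 (−0.70).

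**Figure D2:**
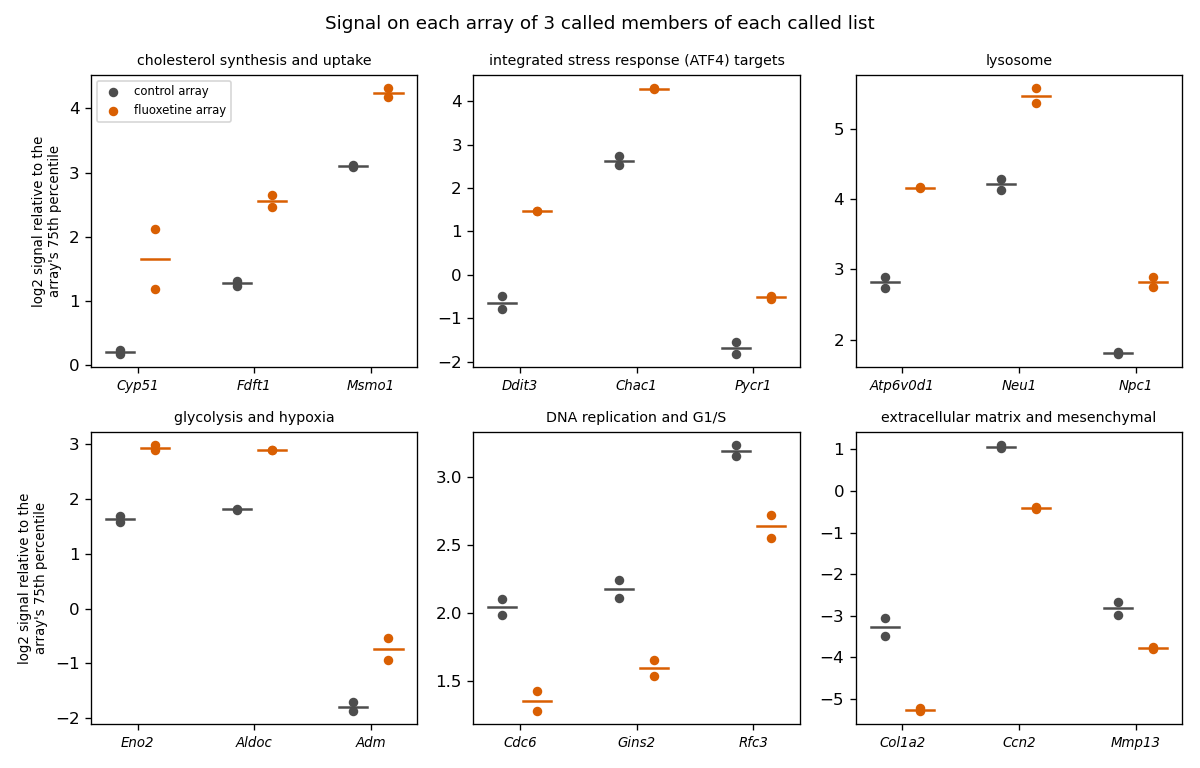
Each point is the log2 signal of 1 array relative to the 75th percentile of that array, for the 3 called members of each of the 6 called lists with the largest change in the direction of the list; short bars are means of 2 arrays. Both fluoxetine arrays lie outside the range of both control arrays for every gene drawn, and Col1a2 was not well above background on either fluoxetine array.

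Extracellular matrix and mesenchymal genes were lower as a list (18 tested, median −0.61, adjusted p = 0.0049; adjusted p = 0.88 with an estimated correlation). In it 8 fell, 1 rose and 9 did not pass, and adjusted over the list alone 11 fell and 2 rose. The collagen gene Col1a2 was at least 2.38-fold lower and not well above background with fluoxetine (adjusted p = 0.0119). The matricellular gene Ccn2 fell by 1.47 ± 0.08 and the collagenase gene Mmp13 by 0.96 ± 0.14. Col6a1 rose (0.56), and the mesenchymal filament gene Vim was at −0.05. With Col1a2 and Cdh2, which is also dim with fluoxetine, set to their bounds, the median stayed at −0.61. Immediate early genes went both ways and were not called as a list (18 tested, median −0.20, adjusted p = 0.291): 8 fell, 4 rose and 6 did not pass, with the same counts adjusted over the list alone. Beside Fos and Egr1, the falls included Egr3 (−0.66) and the phosphatase gene Dusp6 (−0.62), and the rises were Dusp5 (1.25), Klf6 (0.66), Klf4 (0.45) and Jun (0.43).

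Inflammatory cytokines and NF-κB targets were not called as a list (21 tested, median 0.11, adjusted p = 0.423): 7 rose, 2 fell and 12 did not pass, against 8 and 3 adjusted over the list alone. Fry called this list higher (adjusted p = 0.0265). The chemokine genes Cxcl2 (1.52 ± 0.08) and Ccl7 (1.34 ± 0.11) led the rises, and Csf2 (−0.45) and Ptgs2 (−0.46) fell. Of 15 interferon response genes, 3 rose, 1 fell and 11 did not pass, against 6 and 3 adjusted over the list alone (median 0.15, adjusted p = 0.497). Camera did not call this list, and fry called it higher (adjusted p = 0.0309). The listed genes Ifit1, Ifit2, Ifit3, Oas1a, Ifih1, Ifi44 and Ifnb1 were too dim in both groups to be tested. Mx1 and Mx2 had no matched probe. Rsad2, the antiviral protein viperin, rose by 2.06 ± 0.08, Oasl1 by 0.81 ± 0.11 and Irf7 by 0.59, and Cxcl10 fell (−0.41). In the MHC class I presentation list, 2 of 11 rose, 1 fell and 8 did not pass, with the same counts adjusted over the list alone. H2-D1 (0.83 ± 0.09) and Tapbp (0.55) rose and the peptide transporter gene Tap1 fell (−1.20 ± 0.25), with its other kept probe moving the other way. The median of that list (0.01) and its test (higher, adjusted p = 0.958) differed in sign from its mean (−0.01).

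Slc6a4, the serotonin transporter that fluoxetine blocks, rose by 0.60 ± 0.09 (adjusted p = 0.0208). It was 1 of only 4 tested among 21 serotonin and monoamine genes, the others being Htr4 (0.15), Maoa (0.04) and Slc18a2 (−0.30), which did not pass, and the counts were the same adjusted over the list alone. Too few members were tested for camera.

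Many markers of other cell types were not well above background. Of 21 leukocyte markers, 10 were well above background on both control arrays and 9 on both fluoxetine arrays. Among the 11 tested, Cd68, a lysosomal glycoprotein gene (1.39 ± 0.12), and Cd3e (0.52) rose, Itgam fell (−1.96 ± 0.07), and 8 did not pass, against 2 higher and 3 lower adjusted over the list alone (median −0.13, adjusted p = 0.323). Fry called the leukocyte list lower (adjusted p = 0.0396). In this list 2 members were dim in 1 group and have only bounds. The lowest change was −4.76, and the mean (−0.64) lay well below the median. The other kept probes of Cd3e and of Itgam moved the other way. Endothelial markers had 2 tested members of 10, Pecam1 (0.26 ± 0.19) and Tie1 (0.28), and 0 passed, also adjusted over the list alone. Epithelial markers had 7 tested of 11, of which Krt14 fell (−2.15 ± 0.11), 0 rose and 6 did not pass, with the same counts adjusted over the list alone. The epithelial median (0.07) differed in sign from the mean (−0.24) and the test (lower, adjusted p = 0.456). Of 12 common reference genes, 0 passed, also adjusted over the list alone, with Ppia at 0.03 ± 0.09 (median −0.01, adjusted p = 0.681).

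Of 24 lists, camera called 6, of which 4 were higher and 2 lower. With an estimated correlation 0 of the 6 calls held. With fry, which asks whether the genes of a list move one way and does not compare them with other genes, 9 lists were higher and 2 lower. Fry called the 4 higher lists and the extracellular matrix list (adjusted p = 0.027) but not DNA replication and G1/S (adjusted p = 0.0844). Its other lower list was leukocyte markers (adjusted p = 0.0396). Its other higher lists were sterol efflux, endoplasmic reticulum chaperones, p53 targets, interferon response and inflammatory cytokines, with fry adjusted p from 0.0265 to 0.0446.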

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

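The tests on histone and snoRNA genes and on erythroid genes, and the count over splits of the arrays, were chosen after the results they concern were seen. Matching probes on brightness was chosen after the fall it concerns was seen and before its own value was. The alternatives that added unnamed probes, crossed the replicate numbers and left out outlying replicate spots were also chosen then.

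A signal appeared in probes outside the gene counts. Of 8381 tested probes without a gene symbol, 2455 were called in limma, and 129 of them were at least 2-fold higher with fluoxetine than in control, while 1931 of the 2455 were lower and 524 higher. Most named genes that were called had gone the other way (62.3% higher). Relative to the 75th percentile of each array, the median of the unnamed probes was −1.63 and −1.61 on the control arrays and −1.85 and −1.89 on the fluoxetine arrays. Medians of the change were −0.34 over AK cDNA clones, −0.27 over Ensembl transcripts, −0.20 over other accessions and −0.08 over genomic intervals. They were −0.04 over non-coding RNAs of RefSeq and 0.07 over messenger RNAs of RefSeq. The U1 genes Rnu1b6 (−1.56 ± 0.09), Rnu1b1 (−1.45 ± 0.10) and Rnu1a1 (−1.32 ± 0.10), whose near-identical copies one probe may not tell apart, and Rn7sk (−1.32 ± 0.09) fell too.

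For this fall, a lower reading of dim probes on the fluoxetine arrays is argued against: compared with RefSeq messenger RNA probes of like brightness in 20 bins, the unnamed probes differed by −0.26 (bootstrap 95% interval over probes −0.27 to −0.24), close to the −0.29 without matching. A smaller share of RNA without a poly(A) tail in the labelling may account for part of it. The replication-dependent histone genes, mostly without such a tail, had a median of −0.29 (bootstrap 95% interval over genes −0.37 to −0.22), and 13 fell and 2 rose of 41. Over 10 snoRNA genes the median was −0.38 (−0.70 to 0.03), with Snora34 up by 2.69. These intervals hold no spread between arrays. Near-identical histone copies, which one probe may not tell apart, count as separate genes, so the histone interval may be too narrow. The histone median fell just short of the drop that was set as the mark of this explanation, and the snoRNA median reached it with a wide interval. The histone test also stays open because the DNA replication list was lower as well. An effect of fluoxetine itself on these transcripts was not tested apart from labelling.

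The set of called genes as a whole was also weighed. The 3 splits of the 4 arrays into pairs are too few for a share under 0.05: 1 of them, the real one, gave 3653 calls, and the highest of the others gave 0. A brightness-dependent difference in scale between the arrays is argued against as the whole cause, since 94.5% of the called genes were called again after quantile normalization. Hybridisation specific to single probes stays open for part of the calls: of 1316 called genes with a second kept probe, that probe moved the same way in 75.1% (95% interval 72.6 to 77.4), against 59.0% of 3652 genes not called. Fluoxetine itself and the place of the arrays on the slide cannot be told apart by this design, and both may contribute. The control cells were labelled as not treated, so any solvent or handling that came with the drug cannot be told apart either.

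Globin genes rose: Hba-a1 by 2.02 ± 0.09, Hba-a2 by 2.06 ± 0.10 (near-identical copies), Hbb-bt at least 5.68-fold and Hbb-b2 at least 2.20-fold, while Hbb-bh1 (0.74 ± 1.07) did not pass. Red cell RNA in the fluoxetine samples could bring such a rise. Of 16 other erythroid genes, 5 were tested, and Hemgn (0.67) and Klf1 (0.41) rose. The 4 above background on all arrays had a median of 0.34 (95% interval −0.08 to 0.67, the range of the 4 genes), too wide to decide. Hemgn was already bright in control (log2 signal 6.07, against −0.29 for Hba-a1 and −3.66 for Klf1), so its rise says little about red cell RNA. Globin expression by the tumour cells themselves was not tested.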

How the results depend on the processing

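Of 1085 comparisons of a named gene with its value under another setting, 780 kept direction and call, 299 kept the direction but lost the call, and 6 reversed. Outside the 3 settings that called 0 genes, 775 of 851 kept both and 71 lost the call. The called genes that reversed were Hmmr (−0.13) and Atp5b (−0.0025) with the mean over the probes of a gene, since their other probes moved the other way. The others were of Ppia, not called: −0.046 with normexp, −0.0085 with median centring, −0.065 with the mean over probes and −0.047 to 0.11 with 1 array left out. The test of uncalled lists also turned direction: apoptosis regulators (median −0.025 with quantile normalization, −0.033 with the mean over probes), G2/M and mitosis (0.061 with quantile normalization, 0.030 to 0.14 with 1 array left out), respiratory chain (−0.025 with no filter on dim probes) and MHC class I (0.012 with probes above background on all arrays, 0.012 with the replicate block, −0.0055 to 0.19 with 1 array left out); the cause was not tested. Each called list kept its call in every setting except fry and the estimated correlation. With the latter 0 lists were called, 0 higher and 0 lower. Fry called 11 lists, 9 higher, and DNA replication and G1/S lost its call there (adjusted p = 0.0844). Without a filter on dim probes 7 lists were higher, and with the mean over probes 7 also. Under camera, fatty acid synthesis gained a call (normexp, no filter, probes above background on all arrays, mean over probes, crossed pairing). Autophagy (no filter, mean over probes, without control 1) and NRF2 targets (no filter, mean over probes) gained one too. Under fry, sterol efflux, endoplasmic reticulum chaperones, p53 targets, interferon response and inflammatory cytokines gained a call as higher, and leukocyte markers as lower. Counts of genes moved more. With normexp 3687 genes were called, and 284 differed at least 2-fold, 144 higher and 140 lower. That correction added an offset of 50 to every signal, which by arithmetic lowers the fold of dim probes. How much of the drop the offset made was not tested. Without a filter on dim probes limma called 0 genes, 0 higher and 0 lower, of them 0 at least 2-fold, with 5272 of 23771 at an unadjusted p under 0.05; the cause was not tested. With probes above background on all arrays alone, 206 genes were at least 2-fold lower, since genes dim in 1 group leave that test. With 1 array left out in turn, calls ranged from 0 to 2660 (0 to 1701 higher, 0 to 959 lower), at least 2-fold calls from 0 to 1006 (0 to 560 higher, 0 to 446 lower) and called lists from 6 to 7; fewer arrays leave 1 group with a lone array. The replicate number as a block gave 1859 calls, 1085 higher and 774 lower, and 6 lists. The numbers share no stated origin, and control 1 and fluoxetine 1 deviated from their group means with a correlation of −0.12. Crossing the pairing, chosen after seeing the data, gave 2621 calls, and leaving out outlying replicate spots, also chosen then, 3647. Quantile normalization gave 4006 calls, median centring 3779, trend and robust moderation 4889. The slide as a block was not run, since all arrays share 1 slide. Signal over background limits the comparison: 13539 of 23771 genes with a probe were tested.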

Other observations

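The tests on the gene groups below were chosen after seeing the data. Subunits of the vacuolar ATPase, the proton pump of lysosomes, were higher with fluoxetine: 12 of 16 tested rose, 0 fell and 4 did not pass (median 0.48, camera adjusted p = 0.000395 over 7 added lists; adjusted p = 0.34 with an estimated correlation). The group shares Atp6v0d1, Atp6v1a, Atp6v1b2 and Atp6v1h, which all rose, with the lysosome list. It was not tested without them, so it is no separate result from that list. Beside these members, Atp6ap1 rose by 0.78 ± 0.10, Atp6v0a1 by 0.77 ± 0.07 and Atp6v1d by 0.69 ± 0.08. The other kept probe of Atp6v0a1 moved the other way. Genes of folliculin and Rag GTPase nutrient sensing, upstream of mTORC1 at the lysosome, were higher as a group (8 rose, 1 fell and 4 did not pass of 13, median 0.52, adjusted p = 0.000849; adjusted p = 0.34 with an estimated correlation). The group mixes genes that promote mTORC1 with genes that restrain it, such as Nprl2 and Depdc5, so no direction of signalling follows. Nprl2 rose by 1.32 ± 0.08, Rragc by 1.09 ± 0.08, Flcn by 0.99 ± 0.08 and Fnip2 by 0.98 ± 0.11, and Lamtor2 fell (−0.45 ± 0.10).

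Cytosolic aminoacyl-tRNA synthetases, several of them known ATF4 targets, were higher as a group: 8 of 20 rose, 0 fell and 12 did not pass (median 0.31, adjusted p = 0.0027; adjusted p = 0.37 with an estimated correlation). Yars rose by 1.03 ± 0.10, Nars by 0.77 ± 0.09 and Sars by 0.66 ± 0.08, while Wars (−0.01) and Rars (−0.14) did not pass. The other kept probe of Yars moved the other way.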
